A study of Mus musculus with 8 samples.

How the data were processed

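RNA of 8 libraries from mouse skeletal muscle was sequenced, 3 of endothelial cells (EC), 2 of satellite cells (SC) and 3 of single muscle fibres (SMF), grouped by their sample titles, which also give the replicate numbers 1 to 3 (1 and 3 for SC). Per the labels' protocols, EC and SC were sorted by flow cytometry from hindlimb muscles, about 100000 cells for a library, and 100 fibres of the extensor digitorum longus were picked by hand for each fibre library after 3 h of rest. Libraries were made from 10 ng of RNA with a stranded kit that uses random primers and removes ribosomal sequences, and were read as pairs of 50 bp with 20 M reads expected for each, per the labels. The labels state that 1 sample, which they do not name, missed the RNA quality reached by the others.

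Per the submitters' processing notes, the tools were FastQC, Trimmomatic, HISAT2, StringTie and bedtools and the genome build was mm10. Their versions, settings and order are not given in the sources used here, nor is whether strand was used when reads were assigned to genes. Deposited tables of 3 kinds were used. The gene table holds FPKM (fragments per kilobase of transcript, relative to all fragments of the library) for 36048 Ensembl genes in each library, per the file headers. The second table holds TPM (transcript abundance scaled to a fixed total) for 46435 loci, of which 25429 carry identifiers that StringTie made, together with the authors' mean TPM for each population and the authors' specificity score, whose formula is not stated. The transcript table holds FPKM and read coverage for 89871 transcripts as deposited, while the numbers of the transcripts run up to 115219 and 25348 of these numbers are absent from the table. Shares of a gene were therefore computed among the listed transcripts and were not tested. No column of values from other samples was left unused.

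The planned test assumed read counts. Since the gene table holds FPKM, the fallback written in the plan was used in its place: limma with a mean-variance trend on log2(FPKM + 1), all 8 libraries and 1 mean for each group with no covariate, so that the populations share 1 estimate of the spread. Genes with an FPKM of at least 1 in at least 2 libraries were tested (16700 genes), two-sided, and called at a Benjamini-Hochberg adjusted p under 0.05 over these genes. Adjusted p-values in the text are from limma unless camera is named. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Genes enriched in a population passed the joint F-test of limma and lay at least 2 log2 units above the next group. FPKM is relative to all fragments of a library, so the abundant ribosomal RNAs, which differ between the populations, shift all other genes. The main values were kept as deposited, and each count was repeated after median-of-ratios scaling, upper-quartile scaling and scaling without the 50 most abundant genes of each group.

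Before the data were examined, 33 gene lists were fixed, and 31 of them had enough measured members for a test. They cover VEGF ligands and receptors, Notch ligands, receptors and targets, angiopoietins with their receptors and other growth factors. Others hold endothelial, arterial, venous and capillary genes, satellite cell, commitment and cell cycle, and immediate early and stress genes. Further lists are fast and slow fibre, sarcomere, excitation-contraction coupling and neuromuscular junction genes, glycolysis, oxidative phosphorylation, fatty acid, ribosomal protein, basement membrane and hypoxia genes. The rest are markers of fibro-adipogenic progenitors, pericytes, immune cells, erythroid cells, Schwann cells, adipocytes and tenocytes. For each list the members called higher, lower or not at all were counted, over all genes and adjusted over the list alone. Where only the first count is given, the other was equal. The lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data. Genes were named by a rule also fixed before the data were examined. It takes all measured members of the VEGF, Notch and angiopoietin lists, up to 4 members of every other list with the highest mean among those called in the direction of most members, and up to 2 called in the other direction. It also takes, in each direction, the 6 genes with the highest mean among those called at an absolute log2 fold change of at least 3, and the 6 most abundant enriched genes of each population, leaving out predicted genes and short structural RNAs. Members that a sentence singles out because they were not called were named after their values were seen. Tables used the symbols of the deposited files, and 369 of 373 named symbols were located in the RefSeq annotation of GRCm38, the assembly that mm10 names.

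The calculation was tested on simulated data with the means and spreads of the 16700 genes and 50 changed genes at each size. For SC against EC, 36%, 70%, 94% and 94% of genes changed by 1, 2, 3 and 4 log2 units were called, with 7 unchanged genes called. For SC against SMF the shares were 24%, 70%, 84% and 94% with 11. For EC against SMF they were 42%, 86%, 92% and 98% with 13. In this simulation a change of 1 log2 unit was missed more often than it was called. The changed genes were drawn only from genes with higher means, and all other genes were unchanged. In the data 37.65%, 65.07% and 66.34% of genes were called for these comparisons, which makes the adjusted threshold less strict. The shares therefore do not give the sensitivity of the comparisons reported here, nor that for genes with low values. Depth was taken from the ratio of deposited coverage to FPKM, which gives 317.5, 367.8 and 297.8 Mb of aligned bases for EC, 312.9 and 277.9 Mb for SC and 580.8, 570.1 and 525.5 Mb for SMF. No interval from counting was computed, since the tables hold no read counts.

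Other alternatives were a pseudocount of 0.1, a minimum of 5 FPKM, no minimum, the TPM table, a test against a log2 fold change of 1, the 2 groups of a comparison alone, the replicate number as a block, and leaving out each library. The pseudocount of 0.1 on FPKM, the minimum of 5 FPKM and the list counts under the scalings and without each library were chosen after seeing the data. Count-based tests were not run, because the tables used here hold no counts, and transcript usage was not tested for the same reason. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. Globin genes, Hspa1a and Hspa1b, Eef1a1, Gapdh, Eno1, Pgam1 and ribosomal protein genes have near-identical copies or pseudogenes, and Myh8 is a close relative of Myh4. Reads may have been split among copies, and their values are uncertain.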

Results

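RNA sequencing was carried out on 3 populations of mouse skeletal muscle. Endothelial cells (EC, n = 3) line the blood vessels, satellite cells (SC, n = 2, numbered 1 and 3) are the muscle stem cells that lie beside the fibres, and single muscle fibres (SMF, n = 3) are the contractile cells themselves. EC and SC were sorted from hindlimb muscles by flow cytometry, about 100000 cells for a library, while each fibre library held 100 fibres of the extensor digitorum longus, picked by hand after 3 h of rest. The way of isolation and the muscle of origin therefore differed together with the population. The labels do not say that replicates came from separate animals, so the p-values measure only the spread between these 8 libraries, which may be technical. The deposited gene table gives FPKM for 36048 genes, of which 16700 reached an FPKM of at least 1 in at least 2 libraries and were tested. The ratio of deposited transcript coverage to FPKM corresponds to 277.9 to 367.8 Mb of aligned bases in the EC and SC libraries and to 525.5 to 580.8 Mb in the fibre libraries. At these depths, 1 fragment on a transcript of 1 kb is worth 0.272 to 0.360 FPKM in EC and SC and 0.172 to 0.190 FPKM in fibres, and low values carry a matching error. The 10 most abundant genes, mostly RNAs of the ribosome or like them, took 63.7% to 75.1% of all FPKM in EC and SC and 76.2% to 78.9% in fibres. An FPKM of at least 1 was reached by 12640 to 16451 genes in EC and SC libraries and by 7960 to 8116 in fibre libraries. Values are FPKM as mean ± SD over the libraries of a group (n = 3 for EC and SMF, n = 2 for SC), and genes listed at 0 are given per library. The reason is that Tuba1b, a tubulin gene used by all cells, was itself listed at 0 in SMF replicate 3.

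The libraries grouped by population. Spearman correlations across the tested genes, which are not independent replicates, lay between 0.864 and 0.897 among EC libraries, at 0.883 between the SC libraries and between 0.907 and 0.913 among SMF libraries. Mean correlations between populations were 0.602 for EC and SC, 0.576 for SC and SMF and 0.456 for EC and SMF. The first principal component held 65.2% of the variance and the second 22.5%. The transcription factor gene Pax7 (chromosome 4, 139737059 to 139833530, GRCm38, the assembly also called mm10), which marks satellite cells, stood at 93.6 and 118 FPKM in the SC libraries, was listed at 0 in the 3 EC libraries and did not exceed 0.349 in fibres. Cdh5, the cadherin of endothelial junctions (chromosome 8, 104101613 to 104144504), stood at 486 ± 25.2 in EC, 2.84 ± 1.76 in SC and 1.31 ± 0.438 in SMF. Myh4, the myosin heavy chain of the fastest fibres (chromosome 11, 67237812 to 67260447), stood at 8190.0 ± 484 in SMF, 4.32 ± 2.11 in SC and 1.25 ± 1.42 in EC.

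**Figure D1:**
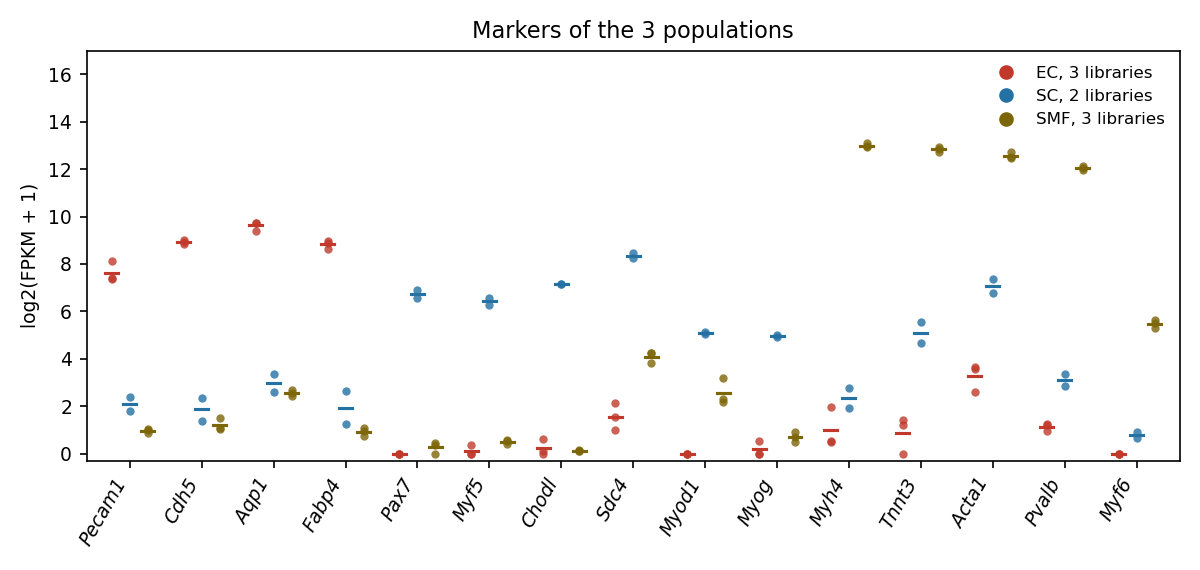
Levels of 15 marker genes in each of the 8 libraries as log2(FPKM + 1), with points for libraries and bars for group means. Pax7 reached 93.6 and 118 FPKM in SC, Cdh5 averaged 486 FPKM in EC and Myh4 averaged 8190.0 FPKM in SMF.

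Satellite cells and endothelial cells, sorted from the same kind of tissue, were compared first. Genes of endothelial identity were higher in EC, with 1 gene not called across 4 lists. Aqp1, a water channel of capillaries (chromosome 6, 55336299 to 55348555), stood at 794 ± 104 in EC and 7.11 ± 2.99 in SC (log2 difference SC minus EC -6.66, SE 0.25, adjusted p = 1.59e-06). The fatty acid carriers Cd36 (542 ± 14.1 against 3.76 ± 3.23) and Fabp4 (458 ± 55.6 against 3.28 ± 2.74) differed by a log2 of -7.02 and -6.90, and Cdh5 by -7.07 (adjusted p = 2.19e-06). All 18 endothelial markers, all 8 arterial genes and all 9 capillary genes were higher in EC, as were 5 of 6 venous genes with 1 not called, and the counts adjusted over the list alone were equal. With the preset correlation, the camera test gave adjusted p = 8.44e-19, 1e-06, 1.26e-09 and 0.00035 for these lists. The endothelial markers kept their call at adjusted p = 0.026 with an estimated correlation, and the others did not (adjusted p = 0.0763, 0.0763 and 0.267 with an estimated correlation). Among them were Pecam1 (204 ± 62.6 against 3.34 ± 1.18) and the phosphatase gene Ptprb (195 ± 26.9 against 2.05 ± 0.929). So were the arterial ephrin gene Efnb2 (47.3 ± 1.16 against 2.15 ± 0.132) and the venous receptor gene Ephb4 (43.3 ± 1.68 against 5.52 ± 0.681). In EC replicate 2 all 6 venous genes stood above both other EC libraries, with Vwf at 91.5 against 22.6 and 20.0 FPKM and Selp at 91.4 against 39.2 and 30.9.

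Satellite cell genes took the other direction. Of 18 satellite cell markers, 16 were higher in SC, 1 was lower and 1 was not called, in equal numbers when adjusted over the list alone (camera adjusted p = 3.31e-11, and adjusted p = 0.0763 with an estimated correlation). The syndecan gene Sdc4 (chromosome 2, 164424247 to 164443188) stood at 326 ± 36.7 in SC and 2.08 ± 1.22 in EC (log2 6.80, SE 0.32, adjusted p = 4.19e-06). Fgfr4, a receptor for fibroblast growth factors, stood at 95.8 and 107 FPKM in SC and was listed at 0 in all 3 EC libraries. Calcr, the calcitonin receptor gene, stood at 26.8 and 28.6 in SC and was listed at 0 in the EC and SMF libraries. Sdc3 was the member with lower values in SC, at 6.41 ± 1.99 against 27.3 ± 4.67 in EC (log2 -1.95, adjusted p = 0.000306). Of 8 myogenic commitment genes, 5 were higher in SC, 1 was lower and 2 were not called (camera adjusted p = 0.00911, and adjusted p = 0.267 with an estimated correlation). The regulator gene Myod1 stood at 33.3 ± 1.72 in SC and at 0 in the EC libraries. Mef2c, a transcription factor gene, was higher in EC at 7.71 ± 2.14 against 0.509 ± 0.246 (log2 -2.51, adjusted p = 0.000293). Of 13 cell cycle genes, 7 were higher in SC, 0 lower and 6 not called (camera adjusted p = 0.0392, and adjusted p = 0.451 with an estimated correlation). The count was 4 higher without SC replicate 3, where the camera call was lost (adjusted p = 0.102). Mki67, a proliferation marker, stood at 17.9 ± 4.32 in SC and 3.76 ± 1.83 in EC (log2 2.05, adjusted p = 0.00265). At an unadjusted p under 0.05, 0 of the cell cycle genes were lower in SC by limma.

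Genes with the most abundant transcripts among those higher in SC included early response genes and metal-binding proteins. Egr1, a transcription factor gene induced within minutes of stimulation, stood at 1137 ± 176 in SC and 139 ± 33.6 in EC (log2 3.04, SE 0.38, adjusted p = 0.000601). The metallothionein gene Mt1 stood at 579 ± 54.7 against 16.9 ± 5.88 and the peroxidase gene Gpx3 at 570.3 ± 6.10 against 9.39 ± 3.89. Of 20 immediate early and stress genes, 14 were higher in SC and 6 not called (15 when adjusted over the list alone, camera adjusted p = 0.000389), and the camera call was lost at adjusted p = 0.409 with an estimated correlation. The count was 8 without SC replicate 1, and 11, 14 and 9 under median-of-ratios scaling, upper-quartile scaling and scaling without the most abundant genes. Fos stood at 1351 ± 320 against 265 ± 54.2 and Junb at 617 ± 103 against 188 ± 44.4. In EC replicate 2, 17 of these 20 genes lay below both other EC libraries (median log2 -0.53). All 20 ribosomal protein genes were higher in SC (camera adjusted p = 3.08e-08, adjusted p = 0.267 with an estimated correlation, 19, 20 and 17 under the 3 other scalings, none lower). Rpl8 stood at 631 ± 29.3 against 207 ± 33.6. In EC replicate 2, 19 of the 20 lay above both other EC libraries (median log2 0.74).

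Many contractile genes were higher in SC than in EC, most of them far below their fibre levels. Of 13 fast fibre genes, 10 were higher in SC and 3 not called (11 when adjusted over the list alone). Of 15 sarcomere and Z disc genes, 11 were higher and 4 not called. Of 12 excitation-contraction coupling genes, 8 were higher and 4 not called (9 when adjusted over the list alone). Camera gave adjusted p = 7.24e-06, 0.00051 and 0.000389, and adjusted p = 0.265, 0.267 and 0.292 with an estimated correlation. Without SC replicate 3, 7 sarcomere and 4 coupling genes were called, and 7 sarcomere genes under the scaling without the most abundant genes. Tnni2, the inhibitory troponin of fast fibres, stood at 21.0 ± 7.54 in SC and 1.84 ± 0.623 in EC against 3185 ± 228 in fibres. Des, the intermediate filament gene desmin, stood at 154 ± 19.6 in SC and 6.45 ± 3.55 in EC (log2 4.52, adjusted p = 0.000147). The skeletal actin gene Acta1 stood at 136 ± 39.3 against 9.21 ± 3.62 (log2 3.79, adjusted p = 0.000135).

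Genes of energy metabolism split between SC and EC. Of 18 glycolysis and glycogen genes, 7 were higher in SC and 11 not called (camera adjusted p = 0.00911, adjusted p = 0.354 with an estimated correlation), and 3 were higher under the scaling without the most abundant genes. Pkm, a pyruvate kinase gene, stood at 98.2 ± 4.77 in SC and 39.6 ± 5.10 in EC (log2 1.29, adjusted p = 0.00106). Of 17 oxidative phosphorylation genes, 7 were higher and 10 not called (10 higher when adjusted over the list alone, camera adjusted p = 0.00911), and adjusted p = 0.409 with an estimated correlation. The count was 4 without EC replicate 2, SC replicate 3 or SMF replicate 3, and 1 under the scaling without the most abundant genes. The ATP synthase gene Atp5a1 stood at 85.1 ± 8.07 against 45.3 ± 4.64, a call that was also lost under that scaling (log2 0.54). Of 14 fatty acid uptake and oxidation genes, 2 were higher, 4 lower and 8 not called (1 and 5 under median-of-ratios scaling, 0 and 5 without the most abundant genes), with a camera adjusted p = 0.229, a median log2 of 0.05 and a mean of -0.99, which differ in sign. Lpl, a lipase of the vessel wall, stood at 11.8 ± 1.32 in SC and 56.6 ± 8.53 in EC (log2 -2.16, adjusted p = 0.00016).

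Matrix, hypoxia and growth factor genes followed. Of 16 basement membrane genes, 2 were higher in SC, 7 lower and 7 not called (2 and 8 when adjusted over the list alone, 1 and 8 without the most abundant genes, camera adjusted p = 0.0297), with adjusted p = 0.462 with an estimated correlation and 0.0699 without SC replicate 3. The laminin gene Lama2 stood at 41.8 ± 1.17 in SC and 0.778 ± 0.629 in EC (log2 4.66, adjusted p = 1.97e-05). The collagen gene Col4a2 stood at 44.7 ± 9.98 against 195 ± 73.2 (log2 -2.04, adjusted p = 0.00338). Of 9 hypoxia-response genes, 4 were lower in SC and 5 not called (5 lower when adjusted over the list alone, camera adjusted p = 0.0102, adjusted p = 0.137 with an estimated correlation). Epas1, the hypoxia-inducible factor of endothelium (chromosome 17, 86753864 to 86833410), stood at 6.64 ± 2.85 in SC and 342 ± 18.8 in EC (log2 -5.54, SE 0.23, adjusted p = 2.33e-06). Of 18 other secreted growth factors, 3 were higher, 7 lower and 8 not called (camera adjusted p = 0.101, and 0.0486 without SC replicate 1). The chemokine gene Cxcl12 stood at 1.72 ± 0.124 in SC and 94.8 ± 27.2 in EC, and the ligand gene Kitl at 1.02 ± 0.489 against 73.6 ± 4.42. Tgfb2 stood at 17.8 ± 3.02 against 4.50 ± 1.55 (log2 1.81, adjusted p = 0.00153). Whether matrix and growth factor RNA of the EC libraries came in part from other cells was not tested.

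Markers of other cell types were measured in the same comparison. Of 8 pericyte and smooth muscle markers, 5 were lower in SC, 1 higher and 2 not called (camera adjusted p = 0.0229, adjusted p = 0.409 with an estimated correlation). Without SC replicate 3 the camera call was lost (adjusted p = 0.0784), and 3 were lower without SC replicate 1 or SC replicate 3. Rgs5, a pericyte marker, stood at 8.25 ± 4.87 in SC and 339 ± 166 in EC (392.3, 153 and 473 in replicates 1 to 3). Of 5 erythroid markers, 3 were lower in SC and 2 not called (5 lower when adjusted over the list alone, camera adjusted p = 0.00857, adjusted p = 0.302 with an estimated correlation), with globin copies that short reads may not tell apart. Of 11 fibro-adipogenic progenitor markers, 2 were higher and 9 not called (camera adjusted p = 0.657), with Dpt, a matrix protein gene, at 99.4 ± 5.60 in SC and 2.69 ± 2.14 in EC (log2 5.02, adjusted p = 0.00125). None of 8 immune cell markers was called by limma (0 at an unadjusted p under 0.05, camera adjusted p = 0.817), and 3 were lower in SC without EC replicate 2 (camera adjusted p = 0.0468). Of 3 tenocyte markers 1 was higher and 2 not called, with a median log2 of -0.72, a mean of 0.31 and a camera adjusted p = 0.708 toward SC. The Schwann cell list had 1 measured member, which was not called by limma in any comparison (0 at an unadjusted p under 0.05), though lower in EC than in SMF under the 3 other scalings, and the adipocyte list had none. Among markers with an EC mean of at least 1 FPKM, all 8 immune, all 9 fibro-adipogenic, all 5 erythroid and 7 of 8 pericyte markers in EC replicate 2 lay below both other EC libraries, by median log2 values of -1.90, -1.73, -1.09 and -1.47.

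**Figure D2:**
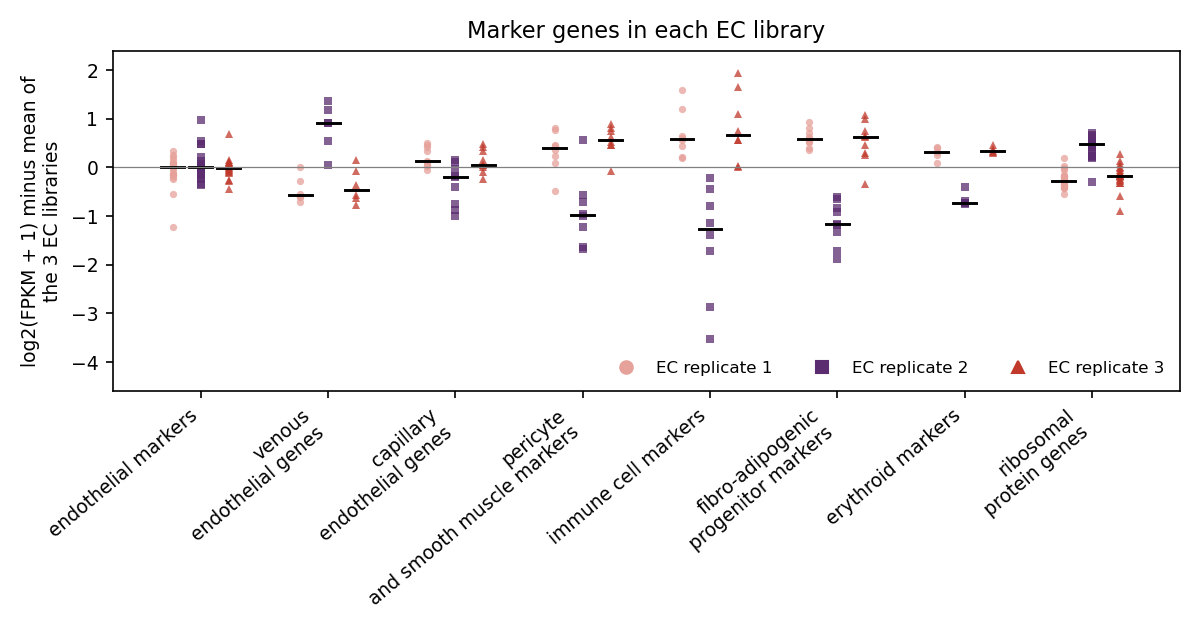
Each point is a marker gene in an EC library, as log2(FPKM + 1) minus the mean of the 3 EC libraries, for 8 marker lists, and black bars are medians over genes with an EC mean of at least 1 FPKM. Among these genes EC replicate 2 lay below the others in 29 of 30 immune, pericyte, fibro-adipogenic and erythroid markers and above them in all 6 venous genes.

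Across all 16700 genes, limma called 3543 higher in SC and 2745 higher in EC, with 10412 not called. The share of calls higher in SC was 56.4%, and 47.9%, 57.2% and 39.1% under median-of-ratios scaling, upper-quartile scaling and scaling without the most abundant genes. Without SC replicate 3, which had 30187 genes above 0 against 23383 in SC replicate 1, the larger side also turned (2441 higher in SC against 2514, 49.3%), as it did in the test against a log2 fold change of 1 (43.9%). The median log2 difference over all genes was 0.11 as deposited and -0.0041 and -0.12 under the first and last of these scalings.

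Satellite cells were next compared with the fibres they lie beside. Genes of contraction were far higher in fibres: Myh4 differed by a log2 of -10.65 (SC minus SMF, SE 0.46, adjusted p = 2.41e-06). Tnnt3, a fast troponin gene (chromosome 7, 142498771 to 142516213), stood at 35.0 ± 14.7 in SC and 7343 ± 506 in SMF. Pvalb, a calcium buffer of fast fibres, stood at 7.69 ± 2.01 against 4269.7 ± 277 (log2 -8.96, SE 0.20, adjusted p = 3.3e-07). All 13 fast fibre genes and all 12 excitation-contraction coupling genes were higher in SMF, as were 14 of 15 sarcomere and Z disc genes (15 when adjusted over the list alone), and the counts did not fall under any of the 3 other scalings. The member not called was Des, at 154 ± 19.6 in SC and 335 ± 20.8 in SMF (log2 -1.12, adjusted p = 0.0518), which was called under all 3 other scalings. Camera gave adjusted p = 5.43e-26, 1.35e-22 and 8.31e-27, and adjusted p = 0.0608 with an estimated correlation for each of the 3 lists. The calcium store gene Casq1 stood at 1.66 ± 0.430 in SC and 918 ± 89.8 in SMF (log2 -8.44, adjusted p = 6.42e-07). The giant protein genes Ttn and Neb stood at 413 ± 125 and 443 ± 90.3 in SMF (log2 -7.10 and -6.76).

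Many genes of energy metabolism took the same direction. All 17 oxidative phosphorylation genes were higher in SMF (median log2 -1.75, camera adjusted p = 3.98e-20, adjusted p = 0.0743 with an estimated correlation), also under each other scaling. Atp5a1 stood at 85.1 ± 8.07 in SC and 204 ± 31.4 in SMF (log2 -1.24, adjusted p = 0.000929). Cox6a2, a respiratory subunit gene of muscle, stood at 411 ± 7.09 in SMF and was listed at 0 and 6.0 in SC. Of 18 glycolysis and glycogen genes, 13 were higher in SMF, 4 higher in SC and 1 not called (2 higher in SC under median-of-ratios scaling, camera adjusted p = 6.84e-12, adjusted p = 0.0782 with an estimated correlation). Aldoa, an aldolase gene, stood at 47.5 ± 5.36 in SC and 1163 ± 97.2 in SMF (log2 -4.58, adjusted p = 1.44e-06). The hexokinase gene Hk1 stood at 18.3 ± 3.11 against 0.137 ± 0.058 (log2 4.08). Of 14 fatty acid genes, 8 were higher in SMF, 3 higher in SC and 3 not called (camera adjusted p = 6.01e-05, adjusted p = 0.161 with an estimated correlation), 5 were higher in SMF without SC replicate 3, and median-of-ratios scaling gave 11 and 1. Cpt1a, which gates fatty acid entry into mitochondria, stood at 22.0 ± 2.01 in SC and 0.244 ± 0.073 in SMF (log2 4.21, adjusted p = 1.74e-06). Its relative Cpt1b, also in the list, was higher in SMF (log2 -3.68), a call that was lost in the TPM table.

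On the SC side stood satellite cell, ribosomal and matrix genes. Of 18 satellite cell markers, 17 were higher in SC and 1 was not called (camera adjusted p = 3.81e-06, adjusted p = 0.161 with an estimated correlation). Chodl (chromosome 16, 78930841 to 78951736) stood at 143 ± 0.90 in SC and 0.077 ± 0.019 in SMF (log2 7.06, SE 0.19, adjusted p = 5.73e-07). Asb5, the member not called as deposited, stood at 102.5 and 54.7 in SC and 78.9 ± 10.7 in SMF, and was called higher in SMF under all 3 other scalings. Of 8 myogenic commitment genes, 4 were higher in SC, 3 lower and 1 not called (4 and 4 when adjusted over the list alone), with a median log2 of 0.42, a mean of -0.39 and a camera adjusted p = 0.09 toward SMF (0.0466 without SMF replicate 2). Myog, the regulator of fusion and differentiation, stood at 30.0 ± 1.48 in SC and 0.625 ± 0.231 in SMF (log2 4.26, adjusted p = 3.99e-06). Myod1 stood at 33.3 ± 1.72 against 5.18 ± 2.53 (log2 2.54, adjusted p = 0.000144), while Myf6, a related regulator, at 0.721 ± 0.216 against 44.0 ± 5.18 (log2 -4.71, adjusted p = 9.27e-07). All 13 cell cycle genes were higher in SC (camera adjusted p = 0.0307, adjusted p = 0.559 with an estimated correlation). The replication gene Mcm3 stood at 5.81 ± 0.884 against 0.374 ± 0.115. All 20 ribosomal protein genes were higher in SC (camera adjusted p = 2.81e-05, adjusted p = 0.54 with an estimated correlation), with 19, 20 and 20 under the other scalings. Rpl8 stood at 631 ± 29.3 against 81.4 ± 9.61. Of 16 basement membrane genes, 15 were higher and 1 not called (camera adjusted p = 0.000965, adjusted p = 0.54 with an estimated correlation), against 12 higher and 1 lower under median-of-ratios scaling. Col4a1 stood at 92.6 ± 6.09 against 1.39 ± 0.441. Of 20 immediate early and stress genes, 19 were higher in SC and 1 not called (camera adjusted p = 0.00128, adjusted p = 0.559 with an estimated correlation), against 14 higher and 1 lower under median-of-ratios scaling. Fos stood at 1351 ± 320 against 135 ± 57.7 (log2 3.38, adjusted p = 0.000136). For this list the way of isolation and the population cannot be told apart. The heat shock genes Hspa1a (1139 ± 365 against 21.2 ± 10.0) and Hspa1b (1341 ± 485 against 54.3 ± 15.5) are near-identical copies, and Eef1a1 (957 ± 63.1 against 7.65 ± 3.06) has many processed copies, so their values are uncertain.

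The remaining lists moved less evenly between SC and SMF. Of 18 endothelial markers, 7 were higher in SC and 11 not called (6 when adjusted over the list alone, camera adjusted p = 0.828), 4 without SC replicate 1, and 1 higher and 1 lower under each other scaling. Arterial genes gave 4 higher and 4 not called (camera adjusted p = 0.763; 1, 3 and 3 higher under the other scalings), and venous genes 2 higher and 4 not called (camera adjusted p = 0.906). Capillary genes gave 2 higher and 7 not called (0 by limma when adjusted over the list alone and 2 at an unadjusted p under 0.05, camera adjusted p = 0.195, and 0.0324 toward SMF without SC replicate 1), against 0 higher and 3 lower under median-of-ratios scaling. Of 18 other growth factors, 14 were higher in SC and 4 not called (camera adjusted p = 0.195), against 9 higher and 3 lower under median-of-ratios scaling, with Thbs2, a thrombospondin gene, at 49.3 ± 23.7 in SC and Igf2 at 38.9 ± 19.2 against 1.24 ± 0.262 in SMF (log2 4.07). Of 9 hypoxia-response genes, 4 were higher, 2 lower and 3 not called (4 and 3 when adjusted over the list alone, camera adjusted p = 0.121), against 1 higher and 4 lower under median-of-ratios scaling, with 4 lower also without EC replicate 3. Camera gave adjusted p = 0.0387 without SC replicate 1. Bnip3, a mitophagy gene, was among the lower, at 2.31 ± 0.850 in SC and 20.8 ± 0.240 in SMF (log2 -2.74, adjusted p = 1.7e-05). Fibro-adipogenic markers gave 3 higher, 1 lower and 7 not called (2 and 1 when adjusted over the list alone, camera adjusted p = 0.195). Pericyte markers gave 3 higher, 1 lower and 4 not called (2 and 1 when adjusted over the list alone, camera adjusted p = 0.996), and immune markers gave 2 higher and 6 not called (camera adjusted p = 0.906). Under median-of-ratios scaling these gave 2 and 2, 2 and 1, and 1 and 0 higher and lower. Without EC replicate 2, whose spread enters the shared error, the lists gave 5, 7 and 6 higher. Erythroid markers gave 2 higher and 3 not called (0 by limma when adjusted over the list alone and 3 at an unadjusted p under 0.05, camera adjusted p = 0.828, 0 higher and 1 lower under median-of-ratios scaling), and tenocyte markers 1 higher and 2 not called (camera adjusted p = 0.492, 0 under median-of-ratios scaling). For the endothelial, capillary, fibro-adipogenic, pericyte and erythroid lists the median and mean were above 0 while camera, which compares a list with all other genes, pointed to SMF. The hypoxia list had a median log2 of -0.11 and a mean of 0.11.

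Over all genes, 9436 were higher in SC and 1431 higher in SMF, with 5833 not called. The share higher in SC was 86.8% as deposited, and 54.9%, 65.0% and 69.2% under the 3 other scalings, while the median log2 difference moved from 0.93 to 0.21 under median-of-ratios scaling.

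Endothelial cells and fibres were the most distant pair. Receptors and channels of endothelium stood high in EC: Aqp1 differed by a log2 of 7.08 (EC minus SMF, SE 0.22, adjusted p = 2.05e-07). Sparcl1, a secreted matrix protein gene, stood at 743 ± 47.1 in EC and 9.34 ± 1.81 in SMF (log2 6.18, adjusted p = 3.45e-07). Fibres held Myh4 at a log2 of -12.00 (SE 0.41, adjusted p = 2.75e-07) and Pvalb, at 1.21 ± 0.267 in EC, at -10.92 (adjusted p = 4.57e-08). The calcium pump gene Atp2a1 stood at 0.650 ± 0.619 in EC and 3137 ± 162 in SMF. All 18 endothelial markers, 8 arterial, 6 venous and 9 capillary genes were higher in EC, also when adjusted over the list alone (camera adjusted p = 8.7e-08, 0.00265, 0.0332 and 0.000457), and adjusted p = 0.0529, 0.131, 0.42 and 0.191 with an estimated correlation. The venous camera call was lost without SC replicate 1 or SC replicate 3 (adjusted p = 0.0711 and 0.0712). B2m, a subunit of class I histocompatibility proteins, stood at 685 ± 228 against 10.7 ± 1.37 (log2 5.83). Tmsb4x, an actin-binding peptide gene, stood at 550.5 ± 103 against 6.43 ± 2.66 (log2 6.27).

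Muscle lists pointed to fibres without exception in the fast fibre (13 of 13), sarcomere (15 of 15), coupling (12 of 12) and oxidative phosphorylation (17 of 17) lists, under every scaling. Camera gave adjusted p = 1.47e-23, 1.62e-24, 1.44e-20 and 1.29e-19, and adjusted p = 0.0529 with an estimated correlation for each of these 4 lists. Of 18 glycolysis and glycogen genes, 13 were higher in SMF, 4 higher in EC and 1 not called (2 higher in EC under median-of-ratios scaling, camera adjusted p = 1.21e-11, adjusted p = 0.0583 with an estimated correlation). The glycogen phosphorylase gene Pygm stood at 2.41 ± 1.09 in EC and 773 ± 57.2 in SMF (log2 -7.88). Of 8 myogenic commitment genes, 6 were higher in SMF, 1 higher in EC and 1 not called (camera adjusted p = 2.07e-05, adjusted p = 0.0874 with an estimated correlation). The gene higher in EC was Cdkn1c, a cell cycle inhibitor, at 26.9 ± 5.48 against 4.64 ± 0.364 (log2 2.29). Of 14 fatty acid genes, 7 were higher in SMF, 4 higher in EC and 3 not called, with a median log2 of -0.48, a mean of 0.41 and a camera adjusted p = 0.0046 toward SMF (adjusted p = 0.232 with an estimated correlation). Median-of-ratios scaling gave 10 and 4. Cd36 (log2 7.11) and Fabp4 (log2 7.92) were higher in EC, and Fabp3, the carrier of heart and muscle, stood at 60.7 ± 11.9 in SMF and was listed at 0 in EC. Of 18 satellite cell markers, 5 were higher in EC, 3 lower and 10 not called, with a median log2 of 0.01, a mean of 0.32 and a camera adjusted p = 0.0332 toward SMF (adjusted p = 0.401 with an estimated correlation). That call was lost without EC replicate 2 (adjusted p = 0.061) and under median-of-ratios scaling (adjusted p = 0.443), which gave 5 higher and 6 lower.

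Ribosomal, early response and matrix genes were compared next, and the first 2 depended on the scaling. All 20 ribosomal protein genes were higher in EC (camera adjusted p = 0.0332, adjusted p = 0.597 with an estimated correlation), but 3 were higher and 1 lower under median-of-ratios scaling (adjusted p = 0.737), 4 and 1 under upper-quartile scaling and 9 and 0 without the most abundant genes. The camera call was lost also without SC replicate 1 or SC replicate 3 (adjusted p = 0.0666 and 0.0679). Of 20 immediate early and stress genes, 16 were higher and 4 not called (camera adjusted p = 0.16, and 0.0172 without SMF replicate 1), against 8 higher and 4 lower under median-of-ratios scaling. Jun stood at 434 ± 66.7 against 65.8 ± 28.4 (log2 2.77, adjusted p = 0.000117). Here too, isolation and population cannot be told apart for the immediate early and stress genes. Of 16 basement membrane genes, 15 were higher and 1 not called (15 and 1 lower under the 3 other scalings, camera adjusted p = 0.000311, adjusted p = 0.292 with an estimated correlation). Col4a1 stood at 228 ± 81.4 in EC (log2 6.52). Of 9 hypoxia-response genes, 6 were higher, 1 lower and 2 not called (camera adjusted p = 0.708), against 3 and 3 under median-of-ratios scaling. Epas1 stood at 342 ± 18.8 against 6.96 ± 0.456 (log2 5.43). Of 18 other growth factors, 14 were higher, 1 lower and 3 not called (13 and 3 under median-of-ratios scaling, camera adjusted p = 0.0324, adjusted p = 0.292 with an estimated correlation, and 0.0634 without SC replicate 1 or SC replicate 3). Cxcl12 (log2 6.20) and Kitl (log2 5.81) were among the higher. Pdgfa, a platelet-derived growth factor gene, was lower at 2.76 ± 0.511 against 6.43 ± 0.308 (log2 -0.99, adjusted p = 0.00048). Of 13 cell cycle genes, 8 were higher and 5 not called (camera adjusted p = 0.332, and 0.0353 under median-of-ratios scaling). In EC replicate 2, 13 of 18 growth factors lay below both other EC libraries and 4 above (median log2 -0.597). Of 15 basement membrane genes with an EC mean of at least 1 FPKM, 11 lay below and 3 above (median log2 -0.403). Whether matrix and growth factor RNA of the EC libraries came in part from other cells was not tested.

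Among markers of other cells, pericyte genes gave 7 higher in EC and 1 not called (7 higher and 1 lower under median-of-ratios scaling, camera adjusted p = 0.106, 0.0203 under median-of-ratios scaling and 0.0135 without EC replicate 2). Rgs5 stood at 339 ± 166 against 3.54 ± 0.630 (log2 6.09). All 5 erythroid markers were higher in EC (camera adjusted p = 0.139). Immune markers gave 5 higher and 3 not called (camera adjusted p = 0.758), but 3 under median-of-ratios and upper-quartile scaling, 2 without EC replicate 1, EC replicate 3 or SMF replicate 2, and 3 without SMF replicate 1. Fibro-adipogenic markers gave 1 higher, 1 lower and 9 not called (0 and 1 by limma when adjusted over the list alone, 1 and 1 at an unadjusted p under 0.05), with a median log2 of 0.65, a mean of 0.21 and a camera adjusted p = 0.0854 toward SMF. They gave 6 higher without EC replicate 2, 0 higher and 3 lower under median-of-ratios scaling, and camera adjusted p = 0.0424, 0.0464 and 0.0218 without EC replicate 1, EC replicate 3 and SMF replicate 1. Tenocyte markers gave 1 lower and 2 not called (camera adjusted p = 0.0975, 0.0447 without SMF replicate 2).

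Over all genes, 9268 were higher in EC and 1811 higher in SMF, with 5621 not called. The share higher in EC was 83.7% as deposited, and 56.1%, 60.1% and 72.8% under the 3 other scalings, with a median log2 difference of 0.85 as deposited and 0.19 under median-of-ratios scaling.

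**Figure D3:**
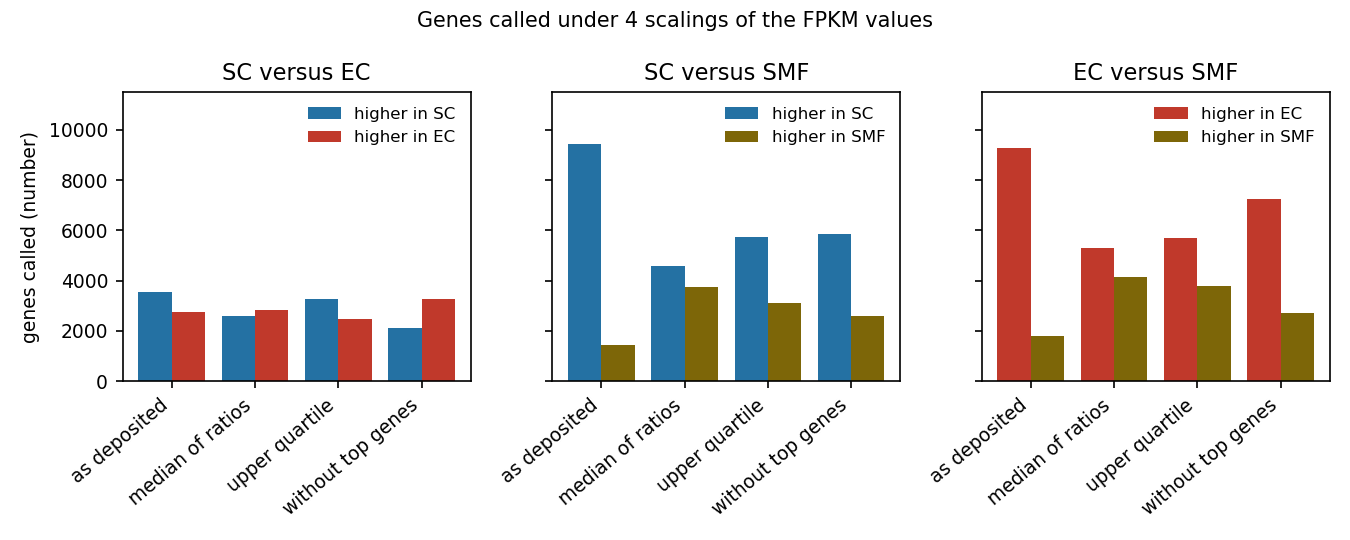
Bars give the number of genes called higher or lower in each of the 3 comparisons under 4 scalings of the FPKM values, as deposited, median of ratios, upper quartile and without the most abundant genes. Calls higher in SC than in SMF fell from 9436 to 4569 under median-of-ratios scaling while those higher in SMF went from 1431 to 3752. In SC against EC the larger side turned from SC (3543 against 2745) to EC (2100 against 3278) without the most abundant genes.

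Genes that set a population apart from both others were taken from a joint test. A difference among the 3 groups was called for 12819 genes (76.8%), and 726, 468 and 401 genes lay at least 2 log2 units above the next population in EC, SC and SMF. The most abundant in EC were Aqp1, Sparcl1, B2m, Cd36, Cdh5 and Igfbp7, the last a binding protein gene at 464 ± 69.3 and 3.84 log2 units above SC. In SC they were Fos, Egr1, Rps3a1, Mt1, Gpx3 and Cyr61, with Gpx3 4.11 units above SMF and Fos 2.34 above EC. Rps3a1, a ribosomal gene with many copies, is uncertain. For the early response genes Fos and Egr1, the way of isolation and the population cannot be told apart against SMF. The call of Mt1 against SMF was lost under median-of-ratios scaling (adjusted p = 0.13). In SMF they were Myh4, Tnnt3, Acta1, Pvalb, Tnni2 and Atp2a1, between 5.50 and 10.65 units above SC. Median-of-ratios scaling gave 198 such genes in SC and 1090.0 in SMF. In the authors' deposited table of specificity scores, Cd36 had the highest score for EC (2.09, with a mean TPM of 458), Chodl for SC (2.21, mean TPM 176) and Myh4 for SMF (3.04, mean TPM 5574).

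Signals of the VEGF family, which direct vessel growth, and of the Notch pathway, by which neighbouring cells instruct each other, were measured gene by gene. Receptors for VEGF were endothelial: Flt1 (chromosome 5, 147561604 to 147726438) stood at 125 ± 4.49 in EC, 0.677 ± 0.126 in SC and 0.362 ± 0.090 in SMF (log2 SC minus EC -6.23, SE 0.14, adjusted p = 4.74e-07). Kdr (chromosome 5, 75932827 to 75979072) stood at 124 ± 38.3, 0.347 ± 0.193 and 0.104 ± 0.036. All 5 receptors were higher in EC than in SC (camera adjusted p = 3.06e-07, and adjusted p = 0.04 with an estimated correlation) and than in SMF (camera adjusted p = 0.00197, adjusted p = 0.0701 with an estimated correlation). Between SC and SMF, 2 were higher in SC and 3 not called (camera adjusted p = 0.906), against 0 higher and 1 lower under median-of-ratios scaling, and the median log2 of 0.30 and camera differed in sign. The ligand gene Vegfa (chromosome 17, 46016993 to 46032377) was lowest in EC at 4.55 ± 0.616, with 27.8 and 11.6 in the SC libraries (log2 1.78, adjusted p = 0.00468) and 35.8 ± 7.01 in SMF (log2 EC minus SMF -2.72, adjusted p = 0.000112). Its lower level in SC than in SMF (log2 -0.93, adjusted p = 0.0408) was lost in the TPM table (log2 -0.78) and in every fit that left out a library other than SC replicate 1, for example at a log2 of -0.34 without SC replicate 3. Vegfb stood at 2.63 ± 0.515 in EC, 7.61 ± 2.06 in SC (log2 SC minus EC 1.23, adjusted p = 0.0027) and 20.9 ± 2.58 in SMF (log2 SC minus SMF -1.36, adjusted p = 0.000743). Vegfc was highest in EC at 10.3 ± 3.72, against 2.85 ± 0.300 in SC (log2 -1.51, adjusted p = 0.00235), and was listed at 0 in all fibre libraries. The 4 measured VEGF ligands gave 2 higher, 1 lower and 1 not called in SC against EC (camera adjusted p = 0.708). They gave 2 higher and 2 lower both in SC and in EC against SMF (camera adjusted p = 0.195 and 0.121), with 1 higher under median-of-ratios scaling in each. In SC against SMF their median log2 of -0.002 and mean of 0.14 differed in sign.

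Angiopoietins, which set the stability of vessels, and their receptors were split likewise. Tek, the receptor gene, stood at 100.0 ± 13.3 in EC, 12.4 ± 0.518 in SC and 0.424 ± 0.304 in SMF (log2 SC minus EC -2.90, adjusted p = 4.07e-05, and SC minus SMF 3.26, adjusted p = 1.22e-05). Angpt2 stood at 16.7 ± 2.15 in EC against 1.26 ± 0.378 in SC (log2 -2.97). Angpt1 was lower in EC at 0.624 ± 0.214, against 2.75 ± 1.07 in SC (log2 1.19, adjusted p = 0.00554) and 2.18 ± 0.503 in SMF (log2 EC minus SMF -0.97, adjusted p = 0.00411). The list gave 1 higher and 3 lower in SC against EC (camera adjusted p = 0.0117, adjusted p = 0.142 with an estimated correlation). It gave 2 higher and 2 not called in SC against SMF (camera adjusted p = 0.762, 1 higher and 1 lower under median-of-ratios scaling) and 3 higher and 1 lower in EC against SMF (camera adjusted p = 0.238).

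In the Notch pathway, Dll4, a ligand of tip and arterial endothelium (chromosome 2, 119325784 to 119335666), stood at 46.1 ± 13.1 in EC, 0.632 ± 0.190 in SC and 0.291 ± 0.183 in SMF (log2 SC minus EC -4.81, SE 0.27, adjusted p = 8.65e-06). Jag2 stood at 11.1 ± 0.499 in EC and 1.1 ± 0.662 in SC (log2 -2.56, adjusted p = 5.31e-05). Dll1 stood at 11.7 ± 4.43 in EC and 6.33 ± 0.438 in SC (adjusted p = 0.0603, called at a log2 of -0.91 without EC replicate 1, and also called without the most abundant genes), and was higher in SC than in SMF, at 0.863 ± 0.187 (log2 1.98, adjusted p = 0.000344). Among receptors, Notch4 was endothelial (11 ± 2.78 in EC against 0.235 ± 0.088 in SC, log2 -3.25, adjusted p = 1.42e-05), while Notch2 was higher in SC (35.0 ± 1.95 against 2.73 ± 0.621, log2 3.28, adjusted p = 8.32e-06). Notch1 stood at 19.7 ± 2.25 in EC and 16.5 ± 1.74 in SC (adjusted p = 0.282, called at a log2 of -0.57 without the most abundant genes). In SMF it stood at 0.172 ± 0.083, below both (log2 SC minus SMF 3.90, adjusted p = 1.81e-06, and EC minus SMF 4.14, adjusted p = 2.71e-07). Notch3 (chromosome 17, 32120820 to 32166896) stood at 63.7 ± 7.02 in SC and at 16.4, 4.0 and 21.6 in the EC libraries (log2 2.36, adjusted p = 0.0127), a call that was lost without SC replicate 1 (log2 2.47) or SC replicate 3 (log2 2.25). Its EC value was lowest in EC replicate 2, as was that of the pericyte marker Rgs5. Whether the Notch3 RNA of the EC libraries came from EC or from other cells was not tested. Among target genes, Heyl (chromosome 4, 123233556 to 123249870) was highest in SC at 73.5 ± 0.919, against 4.2 ± 2.13 in EC (log2 3.94, adjusted p = 0.000115) and 0.182 ± 0.134 in SMF (log2 5.98, adjusted p = 7.98e-06). Nrarp, a feedback inhibitor, was highest in EC at 24.8 ± 1.42 against 1.82 ± 0.013 in SC (log2 -3.19, adjusted p = 5.96e-06). Hes1 stood at 42.4 ± 6.88 and 38.8 ± 0.327 (adjusted p = 0.719).

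Counted by list, 3 of 4 Notch ligands were lower in SC than in EC and 1 was not called (4 lower when adjusted over the list alone, 2 under upper-quartile scaling, camera adjusted p = 0.00416, adjusted p = 0.109 with an estimated correlation). The call of Jag1, at 13.9 ± 1.88 in SC and 19.4 ± 1.73 in EC (log2 -0.45, adjusted p = 0.0474), was lost under that scaling, in the TPM table, with the replicate block and in 6 of 8 leave-one-out fits. Notch receptors gave 2 higher, 1 lower and 1 not called (camera adjusted p = 0.858) and the 5 measured targets 1 higher, 2 lower and 2 not called (camera adjusted p = 0.392). Against SMF, SC had 2 ligands higher and 2 not called (camera adjusted p = 0.624, 2 higher and 1 lower under median-of-ratios scaling). It had 3 receptors higher and 1 not called (camera adjusted p = 0.138, and 0.0166 under median-of-ratios scaling) and 5 targets higher (camera adjusted p = 0.138, 3 higher under each other scaling). EC had all 4 ligands higher than SMF (camera adjusted p = 0.0314, adjusted p = 0.156 with an estimated correlation). It also had all 4 receptors (camera adjusted p = 0.0697, and 3 receptors with 0.0353 under median-of-ratios scaling and 0.0367 without EC replicate 2) and all 5 targets (camera adjusted p = 0.0687, and 4 targets with 0.0353 under median-of-ratios scaling). The receptors include Notch3, whose RNA in the EC libraries may come in part from other cells.

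**Figure D4:**
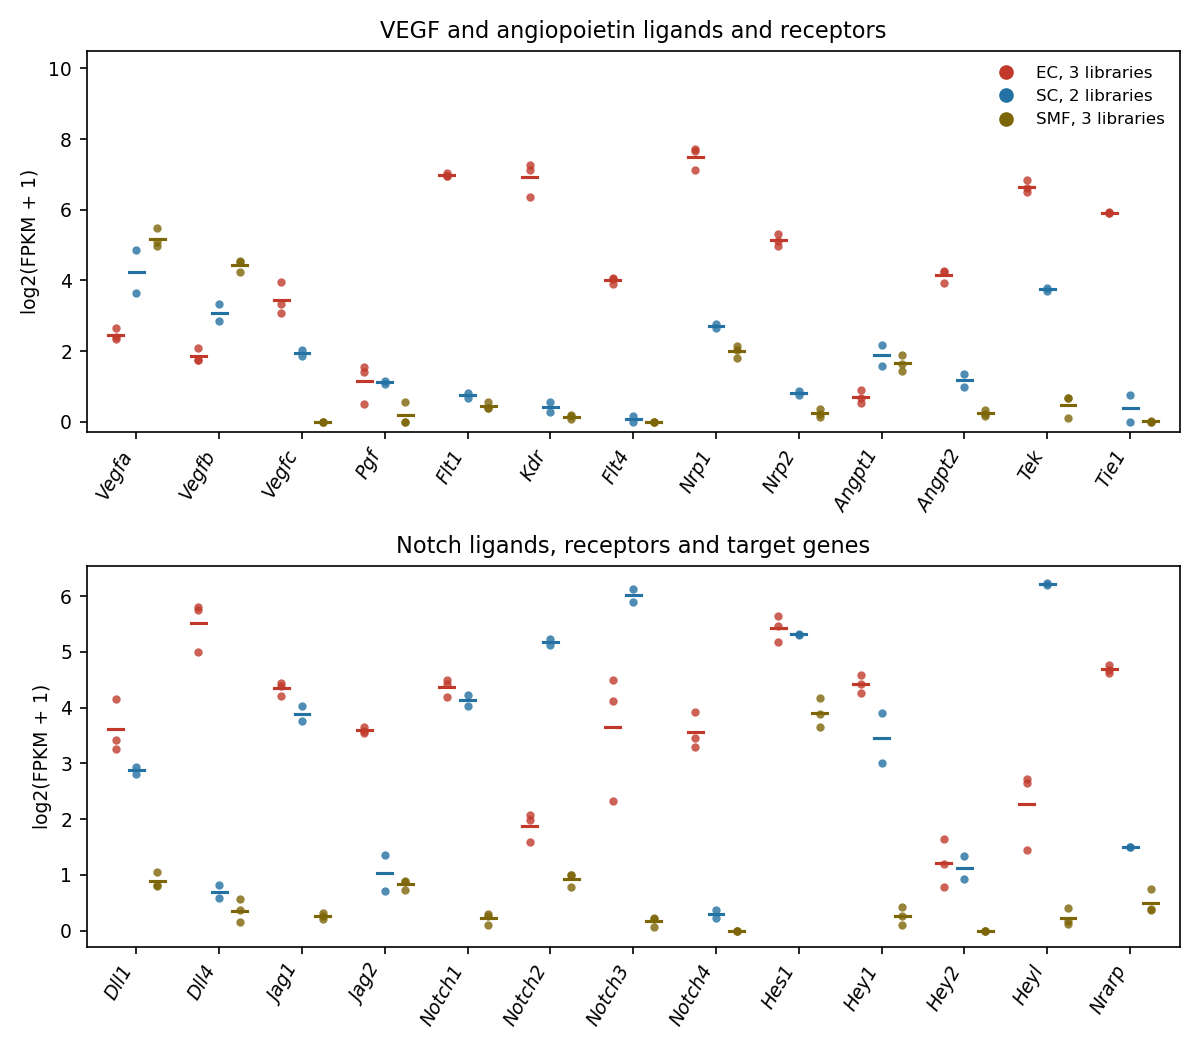
Levels of VEGF and angiopoietin genes (top) and Notch pathway genes (bottom) in each library as log2(FPKM + 1), with points for libraries and bars for group means. Flt1 averaged 125 FPKM in EC and 0.677 in SC, Vegfa 35.8 in SMF and 4.55 in EC, and Heyl 73.5 in SC and 4.2 in EC.

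Transcripts of single genes were described by the deposited transcript table, as shares among the transcripts that the table lists and with no test. Mef2d, a transcription factor gene, was carried in SMF by a transcript of 11 exons (ENSMUST00000107558, chromosome 3, 88142572 to 88168655) at 72.0% ± 1.78, which held 59.0% and 14.7% in the SC libraries and was listed at 0 in EC. Ldb3, a Z disc gene, was carried in SMF by a transcript of 8 exons (ENSMUST00000022330, chromosome 14, 34561253 to 34588681), whose share in SC was 79.2% ± 0.19. In SC it stood at only 1.075 and 1.9 FPKM, and ENSMUST00000022327 at 0.284 and 0.494. The share is therefore uncertain despite its small SD. Tpm1, which encodes tropomyosin, was carried by ENSMUST00000113685 (10 exons, chromosome 9, 67027892 to 67049213) at 72.5% ± 5.14 in SMF, at 0 and 11.4% in SC and at 0 in EC. Tnnt3 was carried by ENSMUST00000179658 in both SMF (98.3% ± 0.20) and SC (95.6% ± 1.08). For Vegfa, a transcript of 7 exons (ENSMUST00000071648) held 94.6% ± 9.31 in EC, 88.9% ± 3.04 in SMF and 0 and 77.9% in the SC libraries. A transcript of 6 exons over nearly the same span (ENSMUST00000167860) held 86.4% at 32.5 FPKM in SC replicate 1 and 0.22% in SC replicate 3. The Vegfa shares in SC are therefore uncertain. Flt1 in EC was carried by its transcript of 30 exons (ENSMUST00000031653) at 97.8% ± 0.59, among 2 listed transcripts of which the other has 3 exons. The transcript numbers next to them are absent, so this share does not show that other forms were lacking. Shares varied widely between replicates for Mef2a, Mef2c, Camk2d, Fn1 and Tpm3, and Pkm, Bin1, Nrp1, Kdr and Dll4 had 1 listed transcript, so no share is given for them.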

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

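The pseudocount of 0.1, the minimum of 5 FPKM and the list counts under other scalings and without single libraries were chosen after seeing the data; the other alternatives were planned. Counts are given as first population / second population, in the order of each comparison's name. Median-of-ratios scaling gave 4569 / 3752 genes for SC against SMF and 5307 / 4160.0 for EC against SMF. Upper-quartile scaling gave 5738 / 3089 and 5685 / 3782, and scaling without the most abundant genes 5863 / 2611 for SC against SMF and 2100.0 genes higher in SC than in EC. These scalings divide all values of a library by 1 factor. A minimum of 5 FPKM gave 2274 / 1815 for SC against EC, 5099 genes higher in SC than in SMF and 5014 higher in EC than in SMF, with fewer genes tested. Against a log2 fold change of 1 the counts were 694 / 887, 3885 / 621 and 3879 / 797 for SC against EC, SC against SMF and EC against SMF, a stricter test by construction. Enriched genes numbered 198 in SC and 1090.0 in SMF under median-of-ratios scaling, 1836, 2104 and 911 in EC, SC and SMF at a gap of 1 log2 unit, and 318, 125 and 216 at a gap of 3. Camera called 22, 11 and 18 of 31 lists and, with an estimated correlation, 2, 0 and 0.

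Directions reversed under median-of-ratios scaling for 12 named results that were called as deposited or under that scaling. Changes of sign in genes called in neither fit were not counted. For SC against SMF these were Nrp1 (-0.57), Jag2 (-0.59), Hes1 (-0.13), Angpt1 (-0.93), Mmrn2 (-0.013) and Hbb-bt (-0.037), and for EC against SMF Fos (-0.39), Eno1 (-0.47), Rpl4 (-0.59), Rpl8 (-0.09), Rplp0 (-0.93) and Arnt (-0.078). A further 35 of 385 named results lost their call there, 17 in the TPM table and 12 with the replicate block, and 47 of 372 with a call lost it in at least 1 fit that left out a library.

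Leaving out each library in turn gave 2441 to 3427 genes higher in SC and 2074 to 3026 higher in EC for SC against EC (2441 / 2514 without SC replicate 3), 7944 to 9848 and 1211 to 1482 for SC against SMF, and 8348 to 9664 and 1633 to 1817 for EC against SMF. There were 711 to 791, 455 to 499 and 380.0 to 421 enriched genes in EC, SC and SMF, and 19 to 23, 11 to 13 and 15 to 20 lists called. Where 1 SC library was left, it was assumed to vary like the other groups. The TPM table, no minimum, a pseudocount of 0.1 and fits of only the 2 groups compared kept the counts of genes within 1.5 times. With the replicate number as a block, the counts were 3040.0 / 2475, 8884 / 1395 and 9236 / 1784 genes, 738, 449 and 413 enriched genes and the same 22, 11 and 18 lists. Whether libraries with the same number shared an animal or a batch is not stated. Correlations of their deviations lay between -0.06 and 0.09. With so few libraries in a group, these values cannot show that nothing else was shared. A count-based tool, the planned CPM minimum and the tests of transcript usage were not run, since the tables used here hold no counts.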

Other observations

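The tests of contractile genes in SC, of Unc45b, of EC replicate 2 and of other splits of the samples were chosen after the results were seen; the gene lists were planned. Several genes of the neuromuscular junction, the contact of nerve and fibre, stood higher in satellite cells than in fibres, but the list as a whole was not called there. Of 9 measured genes, 7 were higher in SC than in EC and 2 not called (camera adjusted p = 9.15e-05, adjusted p = 0.0869 with an estimated correlation). Against SMF 6 were higher in SC, 1 lower and 2 not called (camera adjusted p = 0.828, 5 and 2 under median-of-ratios scaling). The acetylcholine receptor subunit gene Chrnb1 stood at 41.1 ± 8.81 FPKM in SC, 7.13 ± 2.26 in EC and 5.52 ± 0.293 in SMF (log2 SC minus SMF 2.68, adjusted p = 6.97e-05). The kinase gene Musk stood at 14.6 ± 1.49 in SC and 1.39 ± 0.313 in SMF (log2 2.71) and was listed at 0 in EC. Ache, the acetylcholinesterase gene, was higher in SMF at 3.01 ± 0.915 against 1.09 ± 0.026 (log2 SC minus SMF -0.92, adjusted p = 0.00631), a call that was lost in the TPM table (log2 -0.62). In EC against SMF, 6 of the genes were higher in SMF and 3 not called (camera adjusted p = 6.84e-06, adjusted p = 0.0529 with an estimated correlation).

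Of 7 measured slow fibre genes, 6 were higher in SC than in SMF and 1 not called (camera adjusted p = 0.195). Against EC, 5 were higher in SC, 1 lower and 1 not called (camera adjusted p = 0.229, 2 higher and 1 lower under median-of-ratios scaling). In EC against SMF, 3 were higher in EC and 4 not called (camera adjusted p = 0.816). The fibre libraries held fibres of the extensor digitorum longus only, while SC and EC came from hindlimb muscles. For slow fibre genes the muscle of origin and the population therefore cannot be told apart. RNA of slow fibres of other hindlimb muscles was not tested as a source in SC. Myl2, a slow myosin light chain gene, stood at 2.70 and 7.11 in SC and was listed at 0 in all EC and SMF libraries. The calcium pump gene Atp2a2, used by many cell types, stood at 35.4 ± 0.539 in SC and 1.15 ± 0.150 in SMF (log2 4.08, adjusted p = 7.85e-07). Casq2, a calcium store gene, was highest in EC at 12.1 ± 3.39 against 0.345 ± 0.167 in SC (log2 -3.25). Among the fibre libraries, replicate 1 had the tendon genes Thbs4 at 14.9 FPKM against 0.817 and 1.71 and Fmod at 13.0 against 0.627 and 1.24. Fos stood there at 200 against 90.0 and 114.

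The contractile genes seen in SC may come from fibre RNA carried into the sort, or from satellite cells that have begun to differentiate. RNA of fibres with the make-up of the EDL libraries would bring every abundant gene at a like percent of its fibre level. Des is not accounted for by such RNA: it stood at 41.9% and 50.1% of its fibre level in the SC libraries, where no other gene of the fast fibre and sarcomere lists passed 2.04% and 4.75%. Of the 22 other genes of these lists with a fibre mean of at least 100 FPKM, called or not, 19 lay within 5 times of the median percent (0.684% and 0.965%) in both SC libraries. Myoz1, at 0 and 0.636%, lay below that range in SC replicate 1 only. Myh4, the most abundant, stood at 0.0345% and 0.071% and Mybpc2 at 0 and 0.0704%, below the range in both libraries. Such RNA as the whole cause would not bring these 2 genes so low. With only these 2 genes below in both libraries, and Myh4 having close relatives, fibre RNA and expression in SC cannot be told apart for the 22 genes. A few differentiated cells would also bring them together, and cell state was not tested because the labels name none.

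Unc45b, a myosin chaperone gene (chromosome 11, 82911253 to 82943406) that was singled out after its values were seen, stood at 16.4, 15.3 and 17.6 FPKM in EC, near the 28.1, 24.3 and 26.7 of fibres, and at 0.547 and 0.673 in SC. RNA of fibres with the make-up of the EDL libraries is excluded as the whole source. Unc45b reached at least 58.0% of its fibre level in each EC library, while no gene of the fast fibre and sarcomere lists passed 2.65% there. A small part from fibres is not excluded. The neighbour Slfn5 (chromosome 11, 82951349 to 82964850) stood at 102, 109 and 111 FPKM in EC and 2.59 and 0.671 in SC. These levels do not show that the Unc45b signal in EC came from there. In EC the Unc45b transcript that led was ENSMUST00000142336 with 6 exons (82933602 to 82937757), which lies within Unc45b and ends before Slfn5 starts. It held a mean share of 67.3% in EC and was listed at 0 in fibres. ENSMUST00000108160 with 20 exons held 32.7% at 14.5, 13.4 and 14.7 FPKM in EC, against 92.9% at 16.7, 20.2 and 22.3 in fibres. Reads from a transcript that is not annotated and endothelial use of Unc45b itself cannot be told apart with these tables, because they hold no reads.

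EC replicate 2 may hold fewer cells of other types than EC replicates 1 and 3. Of 30 immune, pericyte, fibro-adipogenic and erythroid markers with an EC mean of at least 1 FPKM, 29 lay below both other libraries, for example S100a9 at 5.12 FPKM against 102 and 139 and Pdgfrb at 7.42 against 25.9 and 31.9, while Tagln lay above at 76.0 against 36.3 and 48.8. The sort that selected EC would remove such cells, and free RNA of the digest is not told apart from them. Fewer other cells do not account for the venous genes, whose median lay 1.35 log2 units above that of the endothelial markers (1.37 against 0.02), since these markers would rise alike. In EC replicate 2, 7 of 9 capillary genes lay below both other EC libraries and 1 above (median log2 -0.301). Of 8 arterial genes, 5 lay above both and 2 below (median log2 0.245). A different mix of vessels and a difference in RNA quality stay open and were not tested: the labels do not name the 1 sample that missed the RNA quality, and this library also had 20071 genes above 0 against 24670.0 and 25139, mitochondrial ribosomal RNA at 10.3% of TPM against 5.33% and 6.64%, 19 of 20 ribosomal protein genes above both others and 17 of 20 early response genes below.

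For EC against SMF, 11079 genes were called with the real groups and at most 2 in the other splits of the 6 libraries into groups of 3. The real split is 1 of 10 splits, too few for a share under 0.05. Each other split mixed EC and SMF libraries in both groups, which widens the spread within groups, so few calls were bound to follow. The contrast of these counts therefore decides nothing.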
